A study of Mus musculus with 83 samples.

How the data were processed

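The series holds 83 libraries from a study of paternal heat exposure in mice. Per the labels' protocols, males of 8 to 12 weeks were assigned at random to 7 days of cycled heat, with 8 h at 35 °C and 16 h at 25 °C each day, or to sham housing at a constant 21 °C. Small RNA of 18 to 40 nt was isolated by gel from cauda epididymal sperm (3 control and 3 heat libraries). Polyadenylated RNA was sequenced from single embryos sired by sham or heated males, with 16 control and 18 heat embryos at the 4-cell stage and 22 control and 21 heat embryos at the morula stage. The series' design text calls the sperm samples biological replicates. No label gives the father, mother, litter or day of an embryo, so the p-values for embryos measure the spread between embryos, some of which may share a parent.

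The authors deposited the embryo values as TPM (transcript shares scaled to a fixed sum per library) for 23845 genes. The 77 embryo columns each sum to 1000000 within 0.92, and TPM keeps no depth, so the number of reads behind an embryo value is unknown. The authors deposited the sperm values as raw counts for 2052 features, labelled by class as microRNA, piRNA, tRNA, rRNA or snoRNA. Per the submitters' processing notes, Trimmomatic, Bowtie2, RSEM and mm10 were used, with no versions or roles stated. How reads shared between near-identical features were counted is not given in the sources used here. The deposited counts point to shared reads: 11 tRNA-Gly gene copies have mean counts between 171556 and 177570, and the 45S row has a mean of 1236492 counts beside 942402 for 28S. Counts of features therefore overstate the number of separate molecules.

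Embryo genes were kept where TPM was at least 1 in at least 50% of the embryos of 1 of the groups compared. Values were tested as log2(TPM + 1) with limma 3.58.1 and a mean-variance trend, so fold changes are on the log2(TPM + 1) scale and understate the change of low genes. Each stage was fitted on its own for heat against control. Further fits covered the stage by paternal heat interaction over all 77 embryos and the change from 4-cell to morula in control embryos, for which a gene also needed a log2 fold change of at least 1 in size. Sperm counts were tested with the quasi-likelihood test of edgeR 4.0.16, with TMM scaling and edgeR's default filter. The SE given for a sperm feature is the size of its log2 fold change over the square root of the test's F statistic. All p-values are two-sided, and calls are at a Benjamini-Hochberg adjusted p under 0.05 over the genes or features tested. Polr2a was listed at 0 in 1 embryo and Tbp in 2, so a 0 can be a failed estimate. Gene levels are therefore given as medians with the number of embryos above 0.

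A stage score placed each embryo between the mean 4-cell embryo (0) and the mean morula (1). It is the mean log2 level of 1621 genes higher in morulae less that of 1055 genes lower in morulae, with the genes chosen from all embryos without their paternal treatment. Scores were compared with a permutation test of 100000 resamples and a bootstrap interval of 10000 draws. Shares of sperm RNA classes were compared with an exact permutation test, for which 3 against 3 libraries cannot give a p below 0.1. Intervals for the share in 1 library are 95% Wilson intervals, and the limit given for a class with 0 counts is 3 counts of the library total. Both cover counting error only.

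Before the data were examined, 23 embryo gene lists and 17 small RNA lists were fixed. They were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, for lists with at least 3 tested members. fry asks whether the members of a list move one way on balance and compares them with no other genes. The mitochondrially encoded list has 0 genes in the file. The name patterns of a pair of microRNA lists were corrected after the data were examined, since as first written they also took longer numbers (miR-34 took miR-344); this left 6 members in place of 35 for miR-34 and miR-449 and 8 in place of 194 for muscle microRNAs. MicroRNA rows were matched to lists after their file names were brought to the usual form. The list tests for the change from 4-cell to morula were also added after the data were examined.

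Named genes followed a rule fixed before the data were examined. For each heat comparison it takes the 10 largest changes each way among calls, or all calls if under 20, and with under 10 calls also the 10 smallest p-values. It adds up to 4 members with the smallest p from each list described, the 5 largest changes each way for the stage comparison, and a fixed set (Cdx2, Gata3, Krt8, Pou5f1, Nanog, Sox2, Gata6, Hspa1a, Hspa1b, Hsph1, Zscan4d, Zp3, Gdf9). Of the 23845 symbols, 22552 matched the RefSeq table of GRCm38.p6, the assembly of mm10, as current symbols and 1189 as older ones. Coordinates are from that table.

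Alternatives covered normalization, filters, pseudocounts, array weights, covariates, left-out sperm replicates, DESeq2 1.42.0 for the sperm counts and a block by replicate number. An embryo counted as low when its number of genes above 0 TPM lay over 3 median absolute deviations below its stage's median, which held for 1 embryo (morula control 15). Library depth could not be used for embryos, and count models were not run on TPM. No sperm library was within sampling noise of another of its group (chi-square per degree of freedom of 131 or more). No pair of embryo columns was identical, and the highest correlation within a group was 0.976.

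Each test was tested on simulated data over 10 runs with 100 genes changed at each fold size. For the heat, interaction and score tests the data were embryos with permuted labels, for the stage test control embryos centred within each stage, and for sperm drawn negative binomial counts. At 4-cell, 19.2% of 2-fold and 50.8% of 4-fold changes were called among 7322 genes. At morula the shares were 33.8% and 74.9% among 7897 genes, with a median of 1 false call and 921 in 1 run. For the interaction they were 8.6% and 34.1% among 8689 genes. For the stage comparison 0% of 2-fold changes passed, since the pseudocount takes them below the fold threshold, and 53.7% of 4-fold changes did among 8148 genes. Centring also removed the chance difference between the stage means, so these shares do not give the power on real data. For sperm the shares were 21.4% and 83.8% among 1407 features, with a median of 6 false calls. A shift of the stage score by 0.1 was called in 99 of 100 runs at 4-cell and 92 of 100 at morula, and a shift by 0.05 in 33 and 45. R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were used.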

Results

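Small RNA was measured in cauda sperm of heat-exposed and sham males, and mRNA in single 4-cell embryos and morulae sired with such sperm. The design asks whether a father's week of warmth changes the small RNA of sperm and the transcripts of embryos, and the series title raises the pace of early development. The sperm libraries (3 per group) held between 6429221 and 9936108 counts. The 77 embryo libraries hold TPM with no known depth. The number of detected genes (above 0 TPM) was 8359 ± 1098 in 4-cell control embryos (SD, n = 16) and 8877 ± 979 in 4-cell heat embryos (SD, n = 18). This difference was within the spread between embryos (permutation test, p = 0.155, adjusted p = 0.155). In morulae the number was 10299 ± 1411 in control (SD, n = 22) and 10951 ± 855 in heat embryos (SD, n = 21; permutation test, p = 0.0744, adjusted p = 0.149).

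**Figure D1:**
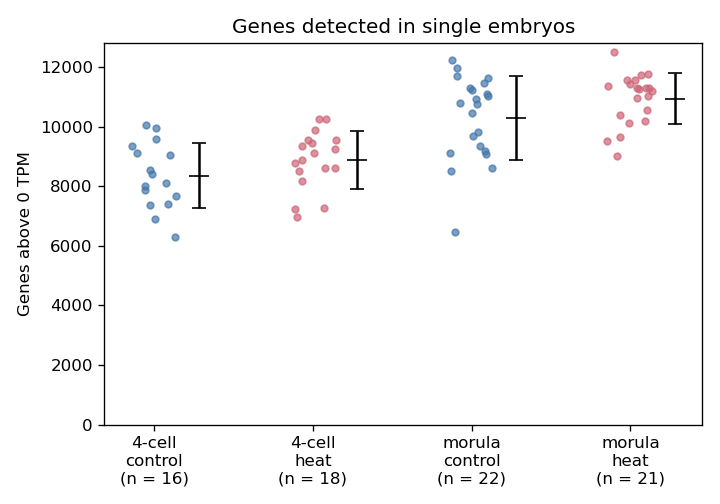
Number of genes above 0 TPM (y axis) in each embryo (points) of the 4 embryo groups (x axis), with the mean and SD beside the points. The heat groups have the higher mean at both stages, 8877 against 8359 and 10951 against 10299, and overlap the control groups widely.

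In sperm, fragments of tRNA were the most abundant class of counts by group mean (in heat replicate 3 it was rRNA), and each heat library had a lower tRNA share than each control library. The share was 52.9 ± 6.71% in control and 39.7 ± 6.21% in heat sperm (SD, n = 3 each; exact permutation test, p = 0.1, the smallest that 3 against 3 libraries can give). Ribosomal RNA had 25.9 ± 1.32% in control and 35.9 ± 12.0% in heat sperm (SD, n = 3 each; exact permutation test, p = 0.1). Heat replicate 3 stood at 49.8% rRNA (Wilson interval 49.77 to 49.83), and without it the rRNA difference was 3.08 in place of 10.0 percentage points. The piRNA share was 6.83 ± 2.77% in control and 11.6 ± 6.07% in heat sperm, with overlapping libraries. Its difference of 4.74 percentage points was 1.68 without heat replicate 2 and 7.75 without heat replicate 3. The microRNA share was 14.3 ± 4.99% and 12.8 ± 2.04%. Its difference of -1.47 turned to 1.37 without control replicate 1 and to 1.19 with rRNA left out of the total. The tRNA difference of -13.3 was -9.36 with rRNA left out (exact permutation test, p = 0.3) and -3.17 over microRNA and tRNA counts alone (exact permutation test, p = 0.6).

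Among tRNA families, tRNA-Glu had 6.91 ± 0.777% of counts in control and 5.38 ± 0.411% in heat sperm. The share of tRNA-Lys was 1.45 ± 0.117% and 0.942 ± 0.159%, and neither family's libraries overlapped between groups. Those of tRNA-Gly (29.9 ± 4.85% and 22.0 ± 3.11%), tRNA-Val and tRNA-His did. No class or family passed after adjustment (smallest adjusted p 0.225 by the exact permutation test over 9 comparisons). The 22 snoRNA features had 0 counts in all 6 libraries, which at a limit of 3 counts allows a share of up to 4.67e-05% in the shallowest.

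**Figure D2:**
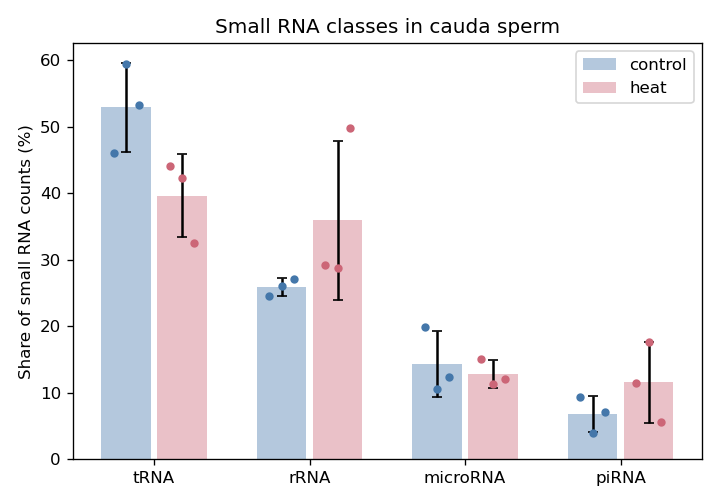
Share of small RNA counts in percent (y axis) of 4 RNA classes (x axis) in control and heat sperm. Points are the 3 libraries of each group, bars their mean and error bars the SD. The control libraries lie above the heat libraries for tRNA, and 1 heat library reaches 49.8% for rRNA.

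No single small RNA passed in sperm, and by edgeR most of the features at an unadjusted p under 0.05 were piRNA transcripts at higher levels after heat. edgeR's quasi-likelihood test called 0 of 1407 features (smallest adjusted p 0.476), with 128 at an unadjusted p under 0.05. DESeq2 called 0, with 10.2% of features at an unadjusted p under 0.05, and limma called 0 with 65. By edgeR, 93 of 457 piRNA features were higher at that unadjusted level and 0 lower, while 17 of the 22 lower features were microRNAs. The piRNA transcripts 14-qA3-284.1 (log2 fold change 1.86, SE 0.52) and 1-qD-2017.1 (1.54, SE 0.49) were among those with the smallest p, none past the threshold. Their heat libraries spread widely (88.2 ± 96.4 and 137 ± 117 CPM, SD, n = 3), with heat replicate 2 the highest for both. The tRNA-Gly genes chr3.trna287-GlyCCC and chr3.trna755-GlyCCC on chromosome 3 had log2 fold changes of 2.57 and 2.52. The former had 93.6 ± 95.2 CPM in control and 558 ± 637 CPM in heat sperm (SD, n = 3 each). All copies of tRNA-GlyCCC summed had -0.59 (SE 0.48). Among the microRNAs, Mir5121 had -1.42 (SE 0.42), Mir96 -1.28 (SE 0.38) and Mir378b -1.22 (SE 0.38). The count of called features was 12 without heat replicate 1, 11 without heat replicate 3, 5 with a stricter filter and 3 with counts scaled to the library total alone. The 93 piRNA features were 2 without heat replicate 2, 6, 15 and 43 without control replicates 2, 3 and 1, and 191 and 178 without heat replicates 1 and 3. They were 109 with DESeq2, 131 with no low-count filter, 31 with limma, 55 with RLE size factors, 53 with a stricter filter and 29 with library totals.

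Several small RNA families ranked below other features as groups in heat sperm, by camera with a preset correlation. The widest group was all microRNAs (406 of 565 lower; adjusted p = 6.39e-22). Next came the tRNA-Lys genes (18 of 20 lower; adjusted p = 1.43e-05) and the tRNA-Val genes (19 of 20 lower; adjusted p = 0.000677). Smaller families were miR-200 (5 of 5 lower; adjusted p = 0.0213), miR-10 with miR-99, miR-100 and miR-125 (8 of 8 lower; adjusted p = 0.025), and the miR-17 cluster (9 of 10 lower; adjusted p = 0.0279). MicroRNAs of the epididymal epithelium, which lines the duct where sperm mature, were lower in 10 of 12 (adjusted p = 0.0254). None of these 7 calls held with an estimated correlation (adjusted p = 0.474 for all microRNAs and 0.751 for the others) or with fry (adjusted p = 0.718). The called microRNA families are parts of the microRNA class, so their calls are not separate from its lower position. That class had a median log2 fold change of -0.27, against 0.36 for piRNA features. With microRNAs fitted alone, the median was 0.07 and 54.9% were higher. TMM scaling was then computed on microRNAs, which centres their fold changes near 0, so that fit cannot test the position of the class. The number of called lists was 4 without control replicate 1 or heat replicate 1, and 13 without control replicate 3 or heat replicate 3.

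Members with the smallest p, none past the threshold, were Mir200b (412 ± 77.1 CPM in control and 195.9 ± 53.6 CPM in heat sperm, SD, log2 fold change -1.07), Mir100 (-0.86), Mir125b-1 (-0.70) and Mir99a (-0.71). Families with no call were let-7 (10 of 15 lower), miR-34 and miR-449 (4 of 6 lower), miR-30 (7 of 7 lower) and the X-linked testis clusters (12 of 21 lower, with Mir741 at -1.38). Blood microRNAs were lower in 3 of 5, with the red cell microRNA Mir486 at 0.89, and muscle microRNAs in 3 of 3. The tRNA-Gly genes were lower in 19 of 29, tRNA-Glu in 14 of 19, and tRNA-His was higher in 11 of 11, with no call. All tRNA genes together were higher in 251 of 379, with a median log2 fold change of 0.14, although the tRNA share of counts was lower. Adjusted over the list alone, 1 epididymal microRNA and 2 tRNA-Gly genes passed, and 0 in the other lists.

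Between the 4-cell stage and the morula, control embryos changed widely, which sets the scale for the paternal comparisons. With limma, 1675 genes rose and 932 fell among 8148 tested (adjusted p under 0.05 and at least 2-fold on the log2(TPM + 1) scale). The largest rise was that of Akr1b8 (median 0.99 TPM at 4-cell and 628 TPM in morulae, log2 fold change 7.39, SE 0.41; chromosome 6, 34354146 to 34368461). S100a11 rose from 1.03 to 288 TPM, the keratin Krt8 from 0.19 to 90.7 TPM (log2 fold change 6.27; chromosome 15, 101996711 to 102004342) and Bmyc from 5.00 to 343 TPM. Fam25c was listed at 0 in 14 of 16 4-cell embryos and had a median of 113 TPM in morulae. The largest falls were those of B020004C17Rik (103 to 0.09 TPM, log2 fold change -6.28), the oocyte genes Omt2b (194 to 2.16 TPM) and Omt2a (79.1 to 0.225 TPM), Fam212a and Septin1.

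Genes of the outer lineage rose together: 20 of 28 tested trophectoderm and compaction genes rose past both limits and 1 fell (camera adjusted p = 7.71e-09). With an estimated correlation that call was lost (adjusted p = 0.193). The trophectoderm factor Cdx2 was above 0 in 5 of 16 4-cell embryos and had a median of 18.1 TPM in morulae (chromosome 5, 147300900 to 147307249). The transcription factor Gata3 rose from 0.59 to 49.6 TPM and S100a10 from 3.08 to 173 TPM. Oocyte and maternal genes went the other way, with 11 of 19 falling and 2 rising (camera adjusted p = 3.37e-07), and this call held with an estimated correlation (adjusted p = 0.00684). Npm2 fell from 90.9 to 3.64 TPM and the zona pellucida gene Zp3 from 34.1 to 8.51 TPM. The oocyte growth factor Gdf9 was above 0 in 14 of 16 4-cell embryos and 7 of 22 morulae, and Gpr3 fell as well. The 2-cell activation genes ranked below other genes, with 4 of 7 falling and 1 rising, such as Obox6 from 1240 to 132 TPM (camera adjusted p = 0.0328; adjusted p = 0.282 with an estimated correlation).

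Stress and metabolic genes ranked above other genes in morulae. Heat shock and chaperone genes rose in 12 of 22 and fell in 0, with Hsp90aa1 at 1199 and then 5211 TPM. Oxidative stress genes rose in 14 of 23, such as the heme oxygenase Hmox1 (log2 fold change 4.33), and cholesterol synthesis genes in 18 of 21. Glycolysis genes rose in 10 of 17 and fell in 1, with Hk2 at 2.97 and Ldhb at -4.47. Oxidative phosphorylation genes rose in 11 of 77 and fell in 1, with Ndufa4 at 1.14. These 5 lists had camera adjusted p-values from 8.71e-06 to 0.0155, and all were lost with an estimated correlation (adjusted p = 0.19 to 0.487). Ribosomal protein genes ranked below other genes with 1 of 85 rising and 1 falling, and Rps13 had -0.64 (camera adjusted p = 0.0137; adjusted p = 0.852 with an estimated correlation).

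Pluripotency genes went both ways (8 rose and 6 fell of 23; camera adjusted p = 0.709). Nanog rose from 4.84 to 63.6 TPM and Pou5f1 from 427 to 1306 TPM, while Klf17 fell from 55.3 to 1.04 TPM. No call was made for primitive endoderm (2 rose, 1 fell of 7), cell cycle (5 and 1 of 39), p53 and apoptosis (4 and 2 of 18), integrated stress response (8 and 0 of 21), chromatin (5 and 4 of 34), imprinted (4 and 2 of 11), microRNA pathway (0 and 0 of 15), cumulus (1 and 1 of 3) or sex-linked genes (0 and 1 of 3). Their camera adjusted p-values ran from 0.267 to 0.907. fry, which compares a list with no other genes, called primitive endoderm (adjusted p = 6.05e-05), integrated stress response (adjusted p = 0.0184) and sex-linked genes (adjusted p = 0.0158). It also called all lists that camera called except ribosomal protein genes (adjusted p = 0.237). Adjusted over the list alone and without the fold limit, 24 of 28 trophectoderm and 17 of 19 oocyte genes passed.

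At the 4-cell stage, no gene differed past the threshold between embryos of heat-exposed and control fathers. Most genes tested lay somewhat higher in heat embryos: the median log2 fold change was 0.26 and 74.1% were above 0. TPM has a fixed sum per library, so this is a shift of shares between genes and not a rise in total RNA. limma called 0 of 7322 genes (smallest adjusted p 0.255), with 842 at an unadjusted p under 0.05, 731 of them higher and 111 lower in heat embryos. The smallest p belonged to Ankrd24 (median 6.90 TPM in control and 1.01 TPM in heat embryos, log2 fold change -1.74, SE 0.37; chromosome 10, 81627821 to 81647612). Others near it, none past the threshold, were Caprin1 (3.45 and 9.46 TPM, 1.16, SE 0.27), Fdx1l (155 and 75.8 TPM, -1.04), 2700038G22Rik (9.11 and 28.1 TPM, 1.35) and the RNA polymerase I factor Taf1c (1.92 and 6.24 TPM, 1.46). The zinc transporter Slc39a13 was above 0 in 12 of 16 control and 5 of 18 heat embryos (-1.25), and Wdhd1, Hars2, 5430405H02Rik and Sntb2 complete the 10 smallest. A fit that pooled the spread of all 77 embryos called 23 genes. With the number of detected genes as a covariate, 491 genes had an unadjusted p under 0.05 and the median log2 fold change was 0.10.

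Among the lists at 4-cell, ribosomal protein genes were lower in heat embryos in 63 of 85 (median log2 fold change -0.10; camera adjusted p = 4.39e-15). They held 27.2% of TPM at 4-cell. With a fixed sum, their lower levels and the higher levels of most other genes may not be separate results. Nuclear-encoded oxidative phosphorylation genes were lower in 47 of 77 (median -0.09; camera adjusted p = 1.27e-08). Neither call held with an estimated correlation (adjusted p = 0.39 and 0.0681) or with fry (adjusted p = 0.327). Among random lists matched on mean level, which can hold the members themselves, the ribosomal median lay at percentile 23.8 and the oxidative phosphorylation median at percentile 0.04. The highest percentiles belonged to lists with no call: integrated stress response (99.92), cell cycle (99.51) and cholesterol synthesis genes (98.59). Examples were Rpl14 (1248 TPM in control and 870 TPM in heat embryos, log2 fold change -0.49, SE 0.15), Rpl24 (-0.27), Uqcr11 (1790 and 1238 TPM, -0.45) and Ndufs5 (-0.35), with Uqcrfs1 at 0.74. The number of detected genes, higher on average in heat embryos, moved with these lists. With it as a covariate the oxidative phosphorylation difference from other genes was -0.12 in place of -0.29, and the ribosomal one -0.18 in place of -0.34. Both calls held with the preset correlation (adjusted p = 0.0445 and 2.53e-08) and neither with an estimated one (adjusted p = 0.799 for both).

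No other list was called at 4-cell. Heat shock genes lay higher in 18 of 22 (camera adjusted p = 0.438), including Hspd1 (0.70, SE 0.31) and Hsph1 (3.45 and 4.44 TPM, 0.45). The inducible Hspa1a and Hspa1b were above 0 in 5 of 16 control embryos each and in 10 and 11 of 18 heat embryos. Integrated stress response genes were higher in 15 of 17 (adjusted p = 0.173; Mthfd2, 1.14) and 2-cell activation genes in 8 of 8 (adjusted p = 0.198; Zfp809, 1.47). Zscan4d, a marker of the 2-cell program, was above 0 in 6 of 16 control and 11 of 18 heat embryos. Genes of p53 and apoptosis were higher in 13 of 14 (adjusted p = 0.198; Bid, 1.51), cell cycle genes in 33 of 38 (adjusted p = 0.198; Ccne1, 1.02) and cholesterol synthesis genes in 13 of 15 (adjusted p = 0.362; Hmgcs1, 0.96). Trophectoderm genes were higher in 14 of 20 (adjusted p = 0.773; Krt8, 0.46). Cdx2 was above 0 in 5 of 16 control and 9 of 18 heat embryos, and Gata3 in 11 of 16 and 11 of 18. Pluripotency genes were higher in 11 of 19 (adjusted p = 0.542), with Nanog at 4.84 and 13.6 TPM (1.29, SE 0.47) and Pou5f1 at 0.16. Sox2 was above 0 in 0 of 16 control and 2 of 18 heat embryos. Primitive endoderm genes were higher in 3 of 3 (adjusted p = 0.968; Gata4, 0.41; Gata6, 0.29, SE 0.56), and oocyte genes in 17 of 20 (adjusted p = 0.773; Zp3, 0.49; Gdf9, 0.51).

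Glycolysis (11 of 13 higher), chromatin (24 of 30), oxidative stress (13 of 19), imprinted (8 of 10) and microRNA pathway genes (12 of 14) had camera adjusted p-values from 0.466 to 0.968 at 4-cell. Adjusted over the list alone, 1 of 8 2-cell activation genes and 2 of 3 sex-linked genes passed, and 0 in the other lists. The 2 are the X-linked Eif2s3x (1.04) and Zfx (0.77), while the third, the Y-linked Eif2s3y, had -0.60 (SE 0.43) and was above 0 in 10 of 16 control and 7 of 18 heat embryos. The summed level of sex-linked genes had medians of 30.3 TPM in control and 49.3 TPM in heat embryos (permutation test, p = 0.0327, adjusted p = 0.327 over 10 comparisons). Sums of cumulus, sperm, blood and fibroblast markers had adjusted p-values from 0.492 to 0.851, and each of these lists had under 3 tested members at this stage.

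In morulae, too, no gene differed past the threshold with paternal heat. limma called 0 of 7897 genes (smallest adjusted p 0.144), with 478 at an unadjusted p under 0.05, 326 higher and 152 lower in heat embryos. The smallest p belonged to Zfp931 (1.62 TPM in control and 0.42 TPM in heat embryos, log2 fold change -0.83, SE 0.18; chromosome 2, 178066446 to 178078425). Others, none past the threshold, were 2200002J24Rik (8.42 and 1.75 TPM, -1.44, SE 0.32), the mitochondrial assembly factor Tmem126a (26.6 and 12.7 TPM, -1.36, SE 0.31), Bet1 (-0.71) and Erdr1 (40.1 and 102 TPM, 1.15, SE 0.28). The testis cytochrome c gene Cyct had 32.4 and 11.7 TPM (-1.37), and Gm14403, Ccdc101, Kcnk4 and Lincenc1 complete the 10 smallest. Lineage genes did not differ past the threshold: Cdx2 had 18.1 and 48.2 TPM (0.71, SE 0.51), Pou5f1 1306 and 1550 TPM (0.54, SE 0.26), Gata3 0.22, Krt8 0.41, Nanog 0.45, Sox2 0.04 and Gata6 0.24. A fit over all 77 embryos called 2 genes. With the number of detected genes as a covariate, the median log2 fold change of all genes was -0.07 in place of 0.13. With Xist and Y-linked levels as covariates instead, that median was 0.25. In that fit 1346 genes had an unadjusted p under 0.05 and 0 were called.

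Of the lists in morulae, oxidative phosphorylation genes were called, below other genes in heat embryos (54 of 77 lower, median log2 fold change -0.12, camera adjusted p = 4.76e-08). This call was lost with an estimated correlation (adjusted p = 0.55) and with fry (adjusted p = 0.735). Ndufb6 (822 and 591 TPM, -0.44, SE 0.16) and Cox7c (-0.39) are examples, with Cox7a1 at 0.85. With the number of detected genes as a covariate the difference from other genes turned from -0.18 to 0.06 and was not called, while ribosomal protein genes were then called above other genes (adjusted p = 4.14e-23; adjusted p = 0.386 with an estimated correlation). Without the covariate, ribosomal protein genes were higher in 58 of 84 (camera adjusted p = 0.443; Rps9, 0.25, SE 0.08). Their test lay above other genes, while their mean was below that of other genes by a difference of -0.05.

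Of all genes tested in morulae, 67.8% were higher in heat embryos, the share to set the list counts against. Heat shock genes were higher in 15 of 22 in morulae (camera adjusted p = 0.945; Hsph1, 0.00, SE 0.29). Hspa1a was above 0 in 11 of 22 control and 12 of 21 heat embryos, and Hspa1b in 10 of 22 and 15 of 21. Trophectoderm genes were higher in 17 of 28, pluripotency genes in 19 of 23 and integrated stress response genes in 18 of 21 (adjusted p = 0.443 for each). Of the maternal and 2-cell genes, Zp3 had -0.09, Gdf9 was above 0 in 7 of 22 and 11 of 21 embryos, and Zscan4d in 2 of 22 and 2 of 21. The remaining lists had adjusted p-values from 0.443 to 0.972. Adjusted over the list alone, 1 microRNA pathway gene passed (Zcchc6, -0.48, SE 0.15) and 0 in the other lists. Sums of cumulus, sperm, blood, fibroblast and sex-linked markers had adjusted p-values from 0.735 to 0.998.

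The effect of paternal heat was not shown to differ between the stages for any gene. The interaction test called 0 of 8689 genes (limma, smallest adjusted p 0.199), with 458 at an unadjusted p under 0.05. As a list, ribosomal protein genes had a higher heat effect in morulae than at 4-cell, by 0.27 on the log2 scale relative to other genes (75 of 85 members; camera adjusted p = 1.16e-13). That call was lost with an estimated correlation (adjusted p = 0.9). The other 18 lists had camera adjusted p-values from 0.156 to 0.846.

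No difference in position along the path from 4-cell to morula was detected with paternal heat. The stage score was 0.00735 ± 0.0727 in 4-cell control embryos (SD, n = 16) and -0.00653 ± 0.0810 in 4-cell heat embryos (SD, n = 18). The heat minus control difference was -0.0139 of the distance between stages (SE 0.0264), with a 95% bootstrap interval from -0.0629 to 0.0368 (permutation test, p = 0.602). Control morulae scored 0.998 ± 0.0990 (SD, n = 22) and heat morulae 1.00 ± 0.0909 (SD, n = 21). Their difference was 0.00487 (SE 0.0290, interval -0.0503 to 0.0599; permutation test, p = 0.867). Both adjusted p-values were 0.867. Embryos were compared within a labelled stage, so the scores do not measure the time taken to reach it. Along the first principal component, put on the same scale, the difference was 0.302 at 4-cell (permutation test, p = 0.114) and 0.201 in morulae (p = 0.362), with a spread within groups of 0.54 and 0.717 (SD).

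**Figure D3:**
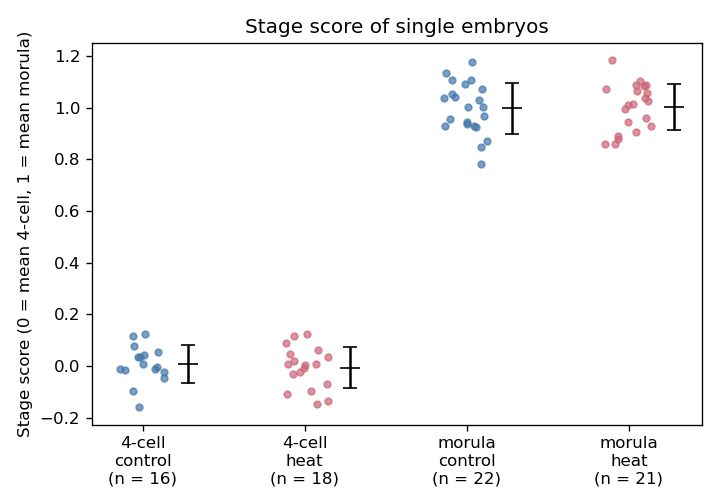
Stage score (y axis, 0 at the mean 4-cell embryo and 1 at the mean morula) of each embryo (points) in the 4 embryo groups (x axis), with the mean and SD beside the points. Control and heat embryos of a stage overlap. At 4-cell, control embryos run from -0.160 to 0.123 and heat embryos from -0.148 to 0.123. In morulae, control embryos run from 0.783 to 1.18 and heat embryos from 0.861 to 1.18.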

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

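Chosen after the result was seen were the tests of detected genes on the 4-cell gene count, of the stage score bound, of level-matched random lists and of the X-linked testis microRNAs, and, as additions to the plan, the list covariate and the piRNA counts without each replicate or with library totals.

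The effect of paternal heat on ribosomal protein genes differed between the 2 stages in the test of that difference, by 0.273 on the log2 scale relative to other genes. The call was made with a preset correlation and was lost with an estimated one (adjusted p = 0.9) and with fry (adjusted p = 0.56). Random relabelling of the embryos within each stage gave a camera p as small as the real one (6.12e-15) in 22 of 100 splits, the real one included, the smallest other being 9.87e-29, so chance cannot be excluded.

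The 4-cell embryos of heat-exposed fathers had 842 genes at an unadjusted p under 0.05, and 7 of 100 splits of these embryos gave as many (highest other 1491), so chance cannot be excluded. Among 4-cell embryos, a mean advance by 0.1 of the way to the morula is argued against by the upper bound of the score difference, 0.0368. However, the first principal component, which spreads by 0.54 (SD) within 4-cell groups, put heat embryos ahead by 0.302 (permutation p = 0.114). Both groups carry the same stage label, so the time taken to reach that stage cannot be compared. With the number of detected genes as a covariate the share of genes at an unadjusted p under 0.05 was 6.71% in place of 11.5%. A difference in how many genes each library detected may account for much of the count. Whether detection differed through the libraries or through the RNA of the embryos stays open, since TPM keeps no depth, as does an effect of the fathers.

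Oxidative phosphorylation genes ranked lower in heat embryos at both stages with a preset correlation, calls lost with an estimated one (adjusted p = 0.0681 at 4-cell and 0.55 in morulae) and with fry (adjusted p = 0.327 and 0.735). Their median lay at percentile 0.04 (4-cell) and 0 (morula) of random lists matched on mean level. Level alone, for genes drawn singly, would thus seldom put them so low. Members move together (estimated correlation 0.0745 and 0.151), which such lists do not carry, so level with shared movement is not excluded. With detected genes as a covariate the difference from other genes was -0.118 in place of -0.29 at 4-cell, 40.6% of its size and still called (adjusted p = 0.0445), and 0.0555 in place of -0.177 in morulae, so detection may carry most of it. Camera p-values as small as the real ones came in 13 of 100 splits at 4-cell (real 1.42e-09, smallest other 1.66e-15) and 24 of 100 in morulae (real 2.64e-09, smallest other 9.78e-25), so chance cannot be excluded. An effect of paternal heat on these genes stays open.

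In sperm, 93 of 457 piRNA features were higher after heat at an unadjusted p under 0.05, and 10 splits of the libraries are too few for a share under 0.05 (128 features of any class in the real split, highest other 159). Without heat replicate 2, which had the highest piRNA share (17.7%), 2 were, so that library may carry much of the pattern, while the count was 6, 15 and 43 without control replicates 2, 3 and 1, and 191 and 178 without heat replicates 1 and 3. With counts scaled to the library total 29 were, under the bound for scaling and rRNA reads, a test added after the piRNA pattern was seen. Scaling and rRNA reads may thus carry part of the count, although the median log2 fold change was 0.39 in place of 0.36. RNA of testicular germ cells cannot be told apart. The X-linked testis microRNAs had a median of -0.15 against 0.36 for piRNA features. This gap of -0.51 passed the bound of 1 SD of members (0.46) but ran from -0.96 to -0.19 as libraries were left out. All tested microRNAs had a median of -0.27, so the gap also holds the difference between the classes and decides little about germ cell RNA. The demand that the gap hold without each library was added after its value was seen, and heat exposure itself stays open.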

How the results depend on the processing

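Chosen after the data were examined were the covariate of detected genes for lists and scores, the class shares without rRNA, summed copies, the list patterns as first written, library totals for sperm lists, the stage genes without the low embryo and the list tests between stages. Genes called at 4-cell (0) and in morulae (0) stayed at 0 under array weights (989 and 901 at an unadjusted p under 0.05, limma), filters, pseudocounts, covariates and the block, but were 23 and 2 in the fit over all 77 embryos. With Xist and Y-linked levels as covariates, 859 genes at 4-cell and 1346 in morulae had an unadjusted p under 0.05 (limma). The interaction stayed at 0 without low embryos and with no low-value filter. Stage genes ran from 2607 to 3753, with 2811 in heat embryos, 1988 of them shared with control embryos in direction. List calls at 4-cell (2) and in morulae (1) were 0 with an estimated correlation and 0 with fry, those in sperm (7) 0 and 0, and those between stages (9) 1 and 11. The oxidative phosphorylation difference at morula turned to 0.0555 with detected genes as a covariate. The stage score difference at 4-cell (-0.0139) was 0.00163 with 200 genes each way and 0.302 along the first principal component. The stage score difference at morula (0.00487) was -0.0084 with 200 genes each way, -0.00611 with genes divided by their SD and -0.0269 with detected genes regressed out. None of these score differences passed. Sperm calls were 3 with library totals, 5 with a stricter filter and 0 to 12 with single replicates left out (12 without heat replicate 1, 11 without heat replicate 3). Sperm list calls ran from 4 (without control 1 or heat 1) to 13 (without control 3 or heat 3). The tRNA share difference (-13.3) was -3.17 over microRNA and tRNA reads. The microRNA share difference (-1.47) was 3.17 over these reads, 1.19 without rRNA and -3.33 to 1.37 with single replicates left out, positive without control 1. Piwil2, called higher in control morulae than at 4-cell without the fold limit, had -0.0783 in heat embryos. The cause of these shifts was not tested. Not run were count models and size factors for embryos, as TPM are not counts, and a pseudocount for sperm counts; no 4-cell embryo was low, so leaving low embryos out has no 4-cell gene count.

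The replicate numbers gave no sign of pairing the samples, though 3 numbers in sperm can hardly test it. Same-numbered deviations correlated at -0.368 to 0.132 in sperm (over 0.1 in 1 of 3 numbers). The range was -0.36 to 0.19 at 4-cell (over 0.1 in 2 of 16 numbers) and -0.447 to 0.736 at morula (over 0.1 in 6 of 21). Samples matched their own number best in 0 of 3, 0 of 16 and 1 of 21. With the replicate block 0 features or genes were called in sperm, at 4-cell and at morula, with 8, 2 and 1 lists, 17 piRNA features were higher at an unadjusted p under 0.05, and the stage score difference was -0.0126 at 4-cell and 0.0114 at morula. Single named genes, and in sperm the called lists, kept their direction in 768 of 772 alternatives at 4-cell, 865 of 889 at morula, 178 of 180 between stages and 961 of 980 in sperm. Of these alternatives, 8, 1, 1 and 20 brought a call and 0, 0, 1 and 14 ended one. The depth behind embryo values is unknown, which limits what can be said of low genes.

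With 0 genes called, every other split gives as many by construction (100 of 100), so the splits test nothing at 4-cell (highest other 1), at morula (1048) and for the interaction (4). The morula split with 1048 calls points to a structure of the samples, but what lay behind that split was not tested. Stage genes were as many in 1 of 100 splits, the real one (2607, highest other 327), so chance is excluded for them. Stage lists were as many in 2 of 100 (9, highest other 9, median other 3). Chance would seldom call so many lists but is not excluded. Lists were as many in 49 of 100 splits at 4-cell (2 and 5) and 90 of 100 at morula (1 and 6), and the ribosomal list at 4-cell had a camera p as small in 11 of 100 (2.44e-16, smallest other 1.15e-39), so chance cannot be excluded. In sperm, 10 splits are too few for a share under 0.05: 5 gave as many lists (7, highest other 15), and with 0 calls (highest other 3) all 10 do by construction.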

Other observations

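The tests of spread in stage scores and the list tests between stages were chosen after the result was seen.

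Imprinted genes went both ways from 4-cell to morula in control embryos (limma, adjusted p under 0.05 and at least 2-fold): Phlda2 fell from 229 to 34.6 TPM (log2 fold change -2.68) and Usp29 fell (-1.15), while Zrsr1 (1.19) and Smoc1 (1.21) rose. Of 9 blood cell markers 2 were tested, too few for a list test, and both fell: the hemoglobin gene Hba-a2 went from a median of 124 to 35.3 TPM (-2.13, SE 0.44) and the lymphocyte gene Cd52 from 8.72 to 1.47 TPM (-1.79, SE 0.53). Among microRNA and small RNA pathway genes (the microRNA pathway list above), Dicer1 (2.64 and 1.17 TPM, -0.70) and Tnrc6a (-0.70) were lower in morulae. The small RNA pathway gene Piwil2 (0.585 and 2.41 TPM, 0.83) was higher. All had limma adjusted p-values of 0.00871 or less and were short of the fold limit. In heat embryos Piwil2 had -0.08, and the difference between treatments did not pass (interaction -0.90, limma adjusted p = 0.905).

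Fold changes for paternal heat at the 4-cell and morula stages, which share no embryos, correlated across 6530 genes tested at both (r = 0.28; genes are not independent replicates), and 67.7% had the same sign. Most genes tested were higher in heat embryos at each stage (74.1% at 4-cell, 67.8% in morulae), which by itself makes equal signs common. Random relabelling gave an r as high in 2 of 100 splits, the real one included (highest other 0.34). Chance would thus seldom give such an r but is not excluded, and relabelling ignores parents that embryos may share. A shared difference between heat and control libraries is a candidate explanation. With the number of detected genes regressed out within each stage the correlation was -0.04, and 62 of 100 splits gave one as high (highest other 0.38). The shared part may therefore follow the number of detected genes, higher on average in both heat groups, which the data do not separate from an effect of the fathers on the embryos' RNA.

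No difference in how widely embryos spread along the stage score was detected: the SD in heat embryos was 1.11 times that of control embryos at 4-cell (permutation p = 0.645) and 0.918 times in morulae (permutation p = 0.657; adjusted p = 0.657 for both).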
